A study of Mus musculus with 24 samples.

How the data were processed

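The 24 RNA-seq libraries came from mouse embryonic fibroblasts (MEFs), connective tissue cells grown from the bodies of embryos. Per the labels, the embryos were male C57BL/6 embryos of day 13.5, and head and inner organs, chiefly heart and liver, were taken out before the tissue was digested with trypsin. The cells were kept in culture for 7 days, then received ethanol vehicle or 1 uM dexamethasone (Dex, a synthetic glucocorticoid) for 16 h. Bacterial lipopolysaccharide (LPS, which triggers innate immune signalling) was given at 100 ng/ul for 6 h to the LPS groups. RNA was purified on columns with a DNase step, and 500 ng went into a stranded mRNA library kit (TruSeq), per the labels' protocols. The labels give 2 genotypes, wild type and the glucocorticoid receptor (GR) mutant named GR Zn/Zn, and 4 treatments, with 3 libraries in each of the 8 groups. Nothing in the labels says that the replicates were separate embryos or cultures, so p-values measure only the spread between these samples, which may be technical. Genotype cannot be told apart from the embryos and cultures that carried it.

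The deposited read counts per gene came from STAR, in the column layout that tool writes for stranded and unstranded counting. The submitters' processing notes name STAR 2.4.2 and 2.4.2a, FastQC, DESeq, DESeq2 and the genome build mm10. The kit reports the strand opposite to the transcript, so the counts of that strand were used. The share of stranded reads on the other strand was 2.70 to 2.91%, and antisense genes were told apart by strand. Entries that name no gene stayed out of library sizes and tests: 3.10 to 4.72% of reads lay in no feature, 3.74 to 5.79% mapped to several places, 2.92 to 5.58% did not map and 1.18 to 1.41% were ambiguous. The authors' deposited tables also give normalized counts, a signal per gene and library scaled by size factors. These were not used as measurements: a comparison with the counts showed that they equal the unstranded counts divided by 1 factor per library for 100% of genes with over 20 reads, within a relative tolerance of 1e-06. The same deposited tables give the authors' log2 fold change and adjusted p-value for each of 12588 genes in 4 comparisons, which are reported beside the values computed here. All genes in those tables had a read in at least 12 libraries. A further 72 columns of values per sample were not used.

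Each library file had 45706 entries that name a gene, of which 27088 had a read in any library. edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, and its default filter by group kept 15221 genes. All 24 libraries entered 1 quasi-likelihood fit with robust estimation and 1 coefficient per group, so that all groups share the estimate of spread. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over the genes tested, and every adjusted p printed for a gene is from this fit unless another tool is named. There were 10 comparisons: Dex in each genotype with and without LPS, LPS in each genotype, the genotype differences of these 3 effects, and the genotypes in vehicle. Levels are given as counts per 1e06 counted reads (CPM) scaled by TMM, as mean ± SD over n = 3 libraries, and log2 fold changes with their standard error (SE). The prior count was 2. Gene positions and biotypes came from GENCODE vM21 on GRCm38, the assembly also called mm10, which held 45143 of the identifiers and 15173 of the tested ones.

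The depth was 18.9 to 25.5 M counted reads in 21 libraries and 43.9 to 58.0 M in 3 others, whose labels carry a later library number series. A count of 0 allows up to 3 reads, which is 0.0518 to 0.159 CPM per library. Such limits and the counting intervals cover counting error only, since no molecular identifiers were used. A fold against a group with 0 reads is written as a bound against 3 reads over the group, and a fold against 1 to 3 reads carries an exact 95% counting interval. Genes that share reads with a near-identical copy (Ifit3 and Ifit3b, Aldh1a1 and Aldh1a7, Tgtp2, Mup3) have uncertain values, since reads mapping to several places were not counted.

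For 20 gene lists the number of members called over all tested genes is given, with the number adjusted over the list alone. The lists are glucocorticoid-induced genes, matrix proteases and AP-1 factors, NF-kB and inflammatory genes, interferon-stimulated genes, extracellular matrix genes, contractile and myofibroblast genes, proliferation genes, circadian clock genes, adipogenic and lipid-storage genes, cholesterol synthesis genes, p53 target and senescence genes, Hox and limb patterning genes, steroid receptor genes, sex-linked genes, and markers of leukocytes, endothelium, epithelium, skeletal muscle, cartilage and bone, and nerve and glia. Each list was tested against the other genes with camera (limma 3.58.1), two-sided, with its preset correlation of 0.01 between genes, adjusted over the 200 tests. Of the 77 tests called, 44 were also called with a correlation estimated for each list, and fry called 93 of the 200. The adjusted p printed beside a list is the estimated-correlation value throughout. Where a list's call at the preset correlation is lost, that value is above 0.05. Members with no read in a group were also set at their bound, which moved a median by at most 0.0338 on the log2 scale.

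The genes named were fixed by rule: 12 genes in every comparison (Nr3c1, Fkbp5, Tsc22d3, Per1, Dusp1, Sgk1, Il6, Ccl2, Cxcl1, Mmp13, Cxcl10, Ifit1), the 8 largest rises and 8 largest falls in 4 comparisons (Dex, Dex under LPS and LPS in wild type, and the genotypes in vehicle), and up to 4 members per list with the smallest p. The largest changes had to be called, to reach an average of 1 on the log2 CPM scale, and to have all 3 libraries of the higher group above all 3 of the lower, which chance gives for 10% of genes. Unnamed gene models were passed over. In a comparison with few calls, all called genes with a symbol are named. The groups, the planned tests, the lists and the rules were set before the data were examined. After the data were seen, 18 transcripts of adult liver were added as a marker list, libraries that stood apart were left out as an added alternative, and the difference of the Dex effect with and without LPS in wild type was added as a comparison. The tests of NF-kB genes in the mutant, of the liver transcripts, of a lower fibroblast share and of the share of the LPS rise were also added then.

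LPS-induced genes were those called with a log2 fold change above 1, chosen in the genotype whose Dex effect was not measured on them. A Dex score per library, the mean log2 CPM of genes higher with Dex in wild type minus that of genes lower, was compared by exact permutation test. The procedure was tested on simulated counts with known changes. For Dex in wild type (14984 genes), 45 of 67 genes changed 1.5-fold were recovered, 59 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 10 of 14755 unchanged genes called. For the genotype difference of the Dex effect (14970 genes) the same numbers were 33 of 67, 46 of 67 and 64 of 66, with 8 of 14741 unchanged genes called. The unchanged genes made up 5.26% and 5.19% of the calls, respectively. On the same simulated counts DESeq2 called more unchanged genes, 21 and 26, beside 173 and 151 changed genes called in the right direction. The changed genes were drawn from genes above a minimum of reads, and the counts were drawn independently, without library-wide shifts by transcript length. Recovery in the real libraries and for genes with fewer reads may be lower. The alternatives tried were DESeq2 1.42.0, other size factors, no filter and a stricter filter, only the libraries compared, the replicate number as a block, library series as a covariate or those libraries left out, unstranded counts, no robust estimation, the level of liver transcripts as a covariate, other thresholds for LPS-induced genes, and leaving out each library in turn. Other computation and plotting used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.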

Results

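RNA of mouse embryonic fibroblasts was sequenced in 24 libraries, 3 in each of 8 groups. Wild-type cells and cells homozygous for GR Zn/Zn, a glucocorticoid receptor altered in a zinc finger of its DNA-binding domain, each received vehicle, Dex, LPS, or Dex with LPS. Each library held 18.9 to 58.0 M counted reads and 19163 to 21362 genes with a read. The first principal component carried 47.9% of the variance and the second 17.8%. Of the 3 libraries deeper than the rest, 1 belonged to each of wild type with Dex and LPS (replicate 3), mutant with vehicle (replicate 1) and mutant with LPS (replicate 2). These 3 also held the most RNA of Alb, the serum albumin gene of liver, among the libraries of their groups, at 152, 133 and 86.5 CPM, in a range of 0 to 152 CPM over all libraries. A further 2 libraries, wild type with Dex and LPS replicate 1 and mutant with Dex and LPS replicate 2, differed from their groups by transcript length, with a rank correlation of deviation with length of -0.662 and -0.656. Between replicates, the chi-square per degree of freedom was 1.56 to 5.05 in the 15 pairs without these 5 libraries and 8.70 to 61.1 in the 9 pairs with at least 1 of them. The pair at 61.1, wild type with Dex and LPS replicates 1 and 3, holds 2 of them. Deviations also followed the share of G and C bases of the transcript, in libraries outside these 5 as well. The rank correlation was 0.656 in mutant vehicle replicate 2 and -0.459 in wild-type vehicle replicate 1. It was -0.555 and 0.614 in mutant Dex replicates 2 and 3. A rank correlation does not give the size of a shift.

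Nr3c1, which encodes GR (ENSMUSG00000024431, chromosome 18, 39410545 to 39519421 on mm10), was expressed at 89.7 ± 2.94 CPM (SD, n = 3) in wild-type and 86.5 ± 1.11 CPM in mutant vehicle cultures. The genotypes differed by a log2 of -0.05 ± 0.12 (SE, adjusted p = 0.847). A count per gene does not show whether the mutation is present, so Nr3c1 checks the expression of the receptor and not the genotype labels. In wild type Nr3c1 fell 1.53-fold with Dex, to 58.5 ± 2.19 CPM (log2 -0.62 ± 0.13, adjusted p = 0.00142), and it fell under LPS as well (log2 -0.56 ± 0.13, adjusted p = 0.00237). In the mutant it was at 79.5 ± 1.66 CPM with Dex (log2 -0.12 ± 0.12, adjusted p = 0.799), and the genotype difference of this effect did not pass the test (log2 0.50 ± 0.18, adjusted p = 0.113).

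Dex raised the best-known glucocorticoid target genes of wild-type fibroblasts. Fkbp5, which encodes a chaperone partner of GR (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527), rose 7.44-fold, from 41.3 ± 1.40 to 307 ± 13.2 CPM (SD, n = 3; log2 2.89 ± 0.06, adjusted p = 8.43e-20). Tsc22d3, which encodes the anti-inflammatory protein GILZ (chromosome X, 140539528 to 140600659), rose 5.65-fold, from 22.2 ± 0.745 to 125 ± 3.06 CPM. The clock gene Per1 rose 4.19-fold, the kinase gene Sgk1 2.78-fold and the phosphatase gene Dusp1 1.38-fold. The largest rises were in Zbtb16, a zinc finger repressor (151-fold, to 14 ± 0.755 CPM), Fam107a (50.5-fold), Map7d2 (27.2-fold), the metallothionein Mt2 (10.9-fold), periplakin (Ppl, 12.1-fold) and the iron-binding lipocalin Lcn2 (8.84-fold). Aldh1a7 (29.7-fold) and Aldh1a1 (9.44-fold) rose too, but their values are uncertain, since these retinaldehyde dehydrogenase genes share reads. Of 31 tested glucocorticoid-induced genes 26 rose and 2 fell (27 and 2 adjusted over the list alone), with a median log2 of 1.08 and an adjusted p of 6.37e-10. In all, 2003 of 15221 genes were called, 1205 higher and 798 lower, of which 236 and 136 changed at least 2-fold.

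Genes that fell with Dex in wild type included the cytokine Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), which went from 2.17 ± 0.0715 to 0.706 ± 0.249 CPM (3.15-fold lower, adjusted p = 6.78e-06). Other large falls were Neurl3 (5.71-fold lower), the histidine transporter Slc15a3 (5.66-fold), the chemokine Ccl4 (4.51-fold), the Notch target Heyl (3.43-fold), Sema7a (3.17-fold), Fam167a (log2 -2.19) and Unc13c (log2 -1.68). Of 35 NF-kB and inflammatory genes 11 fell and 2 rose (11 and 3 adjusted over the list alone). This call was lost at an adjusted p = 0.154 with an estimated correlation, and the median (-0.12) and mean (0.01) of the list differ in sign. The members that fell included the prostaglandin synthase Ptgs2 (log2 -1.26), the chemokine Cx3cl1 (log2 -1.17), Lif (log2 -0.54) and Ccl2 (log2 -0.44). The neutrophil chemokine Cxcl1 rose (log2 0.68, adjusted p = 0.00665). Cxcl10, Ifit1 and Mmp13 had log2 changes of -0.22 ± 0.33, 0.15 ± 0.46 and 0.39 ± 0.75 and were not called. The sign for Mmp13 rests on Dex replicate 3, with 0.764, 0.372 and 7.48 CPM with Dex against 3.66, 1.48 and 1.03 with vehicle. Among matrix proteases and AP-1 factors 5 of 19 fell and 2 rose (7 and 3 adjusted over the list alone). The plasminogen activator Plat (log2 -0.95) and stromelysin Mmp3 (log2 -0.67) fell, and the aggrecanase Adamts1 (log2 1.34) and Fos (log2 0.47) rose. That list was not called.

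Of 22 cholesterol synthesis genes 17 rose and none fell with Dex in wild type (20 and 0 adjusted over the list alone), among them Lss (log2 0.62), Msmo1 (0.48), Sqle (0.38) and Cyp51 (0.32), with an adjusted p of 2.92e-05. Adipogenic and lipid-storage genes rose in 6 of 20 members and fell in 1 (8 and 3 adjusted over the list alone; adjusted p = 0.0331). Those that rose included the fatty acid carrier Fabp4 (log2 2.49) and the transcription factors Klf15 (2.53) and Cebpa (0.53), while the lipid droplet gene Plin2 fell (-0.26). Klf15 and Cebpd are also on the glucocorticoid-induced list, and Per1 is on both that list and the clock list. The adipogenic and clock lists are thus not independent of the glucocorticoid-induced list in any Dex comparison. Of 19 clock genes 7 rose and 2 fell (8 and 5 adjusted over the list alone; adjusted p = 0.0492), at a median of 0.03 in wild type and also 0.03 in the mutant, with 10 members not called in wild type by edgeR. Per2 (log2 2.46) and Cry1 (1.40), which repress the clock, rose, and Nr1d1, which encodes REV-ERB alpha, fell (-1.60). Contractile and myofibroblast genes rose in 10 of 24 members and fell in 3 (12 and 3 adjusted over the list alone), with rises of Lmod1 (log2 0.81), the integrin Itga5 (0.77) and Ctgf (0.61), but at an adjusted p = 0.117 with an estimated correlation. Of 12 steroid receptor genes 4 fell, including the receptors Esr1 (log2 -1.61) and Pgr (-0.91) (5 adjusted over the list alone), at an adjusted p = 0.154 with an estimated correlation. The epithelial markers Cldn4 (log2 -1.69) and Krt18 (-0.47) fell out of 4 tested, also 2 adjusted over the list alone, at an adjusted p = 0.162 with an estimated correlation. The cartilage and bone markers Col11a1 (log2 1.31) and Hapln1 (1.87) rose and Spp1 (-0.46) fell out of 18 tested (3 and 1 adjusted over the list alone), at an adjusted p = 0.562 with an estimated correlation. In 1 library, wild-type Dex replicate 3, the mean log2 CPM of this list was 3.81, against 2.55 and 2.57 in the other 2 and 2.32 to 2.61 with vehicle. Of the 18 adult liver markers none was called in this comparison by edgeR, and their median log2 was -1.94. With all but the compared libraries left out the fit called 4697 genes, and without the 5 libraries that stood apart it called 4331.

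None of these genes passed the test in the GR mutant. Fkbp5 stayed at 44.8 ± 0.807 CPM with vehicle and 44.0 ± 2.38 CPM with Dex (SD, n = 3; log2 -0.03 ± 0.05, adjusted p = 0.898). Tsc22d3 stayed at 26.7 ± 0.960 and 27.8 ± 2.28 CPM, and Per1 at 22.8 ± 3.32 and 23.6 ± 0.639 CPM. Zbtb16 was at or below 0.333 CPM in each mutant library with vehicle or Dex. Il6 was at 2.43 ± 0.304 and 1.78 ± 0.312 CPM (log2 -0.48 ± 0.16, adjusted p = 0.675). edgeR called 0 of 15221 genes at a smallest adjusted p of 0.140, with 1109 genes at an unadjusted p below 0.05. DESeq2 called 3. Over the 2003 genes called in wild type, the Dex score moved by 1.28 in wild type and by 0.0276 in the mutant (95% interval of the mutant change -0.0112 to 0.0664). The genes were chosen in the same wild-type libraries, which inflates the wild-type values of the score and of the medians below. The exact permutation test of the mutant score gave p = 0.2, and 3 libraries against 3 cannot give a p below 0.1. Genes higher with Dex in wild type had a median log2 of 0.45 there and 0.01 in the mutant, and genes lower had -0.47 and -0.02. Among the gene lists, p53 target genes ranked slightly higher with Dex in the mutant (median log2 0.05, adjusted p = 0.0132), with no member called by edgeR over all genes or adjusted over the list alone. Interferon-stimulated genes had a median log2 of -0.28, with 0 members called (5 lower adjusted over the list alone), at an adjusted p = 0.303 with an estimated correlation. Shifts of extracellular matrix genes (adjusted p = 0.305 with an estimated correlation), matrix proteases (0.174), proliferation genes (0.139), adipogenic genes (0.132) and Hox genes (0.0933) were lost in the same way, with no member called by edgeR and 1 protease higher adjusted over the list alone. The liver markers had a median log2 of -2.96 in this comparison, with none of 18 called by edgeR.

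**Figure D1:**
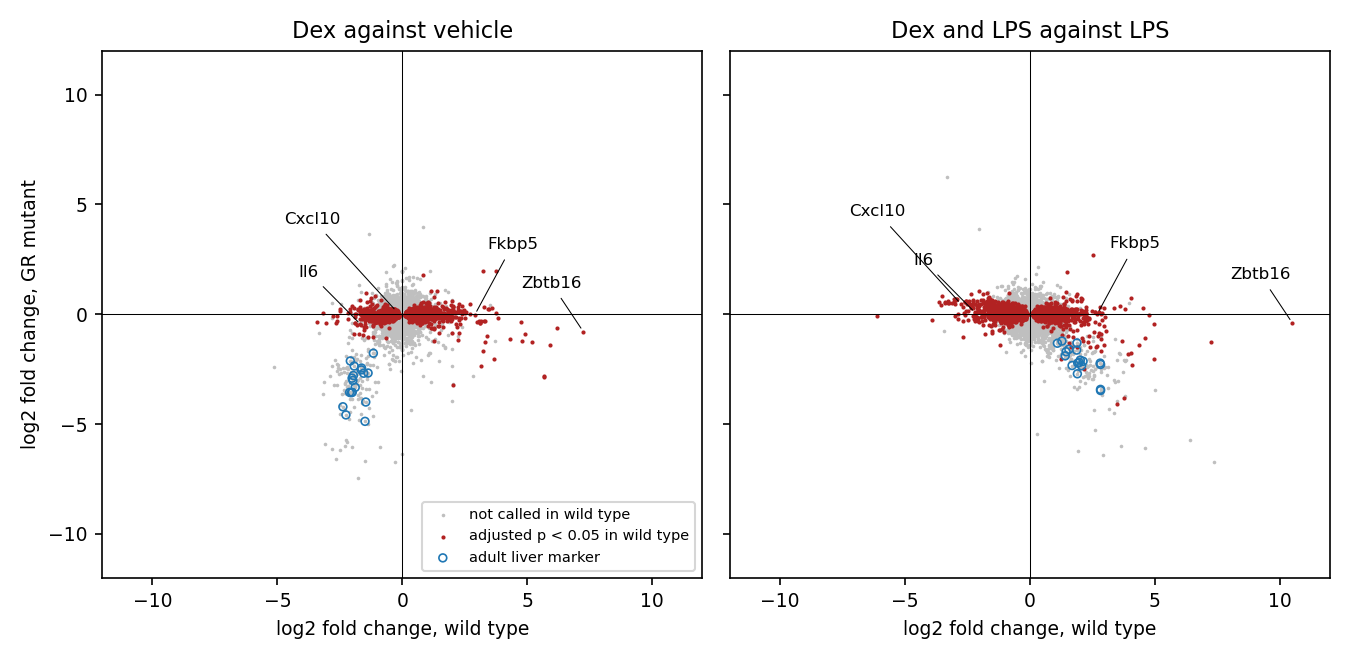
Fitted log2 fold change of each of 15221 tested genes in wild type (x axis) and in the GR mutant (y axis), for Dex against vehicle (left) and for Dex with LPS against LPS (right). Red points, 2003 and 3198 genes called in wild type, spread along the x axis and mostly stay near 0 on the y axis, while circled adult liver markers also vary along the y axis. The 33 interferon-stimulated genes, red in the right panel, have a median of 0.46 on the y axis.

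The test of the difference itself called 1064 genes, 395 with a higher and 669 with a lower response to Dex in the mutant. In this and the later genotype differences, a higher response means a log2 change that is more positive in the mutant. It can stand for a fall in wild type that was smaller or absent in the mutant, as for Il6. The responses of Fkbp5 (log2 difference -2.92 ± 0.08), Tsc22d3 (-2.45 ± 0.09), Per1 (-2.00 ± 0.13), Sgk1 (-1.46 ± 0.07) and Dusp1 (-0.40 ± 0.09) were lower. So were those of Glul (-1.48 ± 0.08), Per2 (-2.34 ± 0.16), Fabp4 (-2.65 ± 0.19) and Klf15 (-2.42 ± 0.30). Il6 (1.17 ± 0.28), Cx3cl1 (1.22 ± 0.09), Ptgs2 (1.13 ± 0.18), Plat (0.94 ± 0.06) and Nr1d1 (1.52 ± 0.10) had higher responses. Of the 31 glucocorticoid-induced genes 22 had a lower and 2 a higher response (24 and 2 adjusted over the list alone; median log2 -0.94, adjusted p = 7.07e-10). A lower response was also called for 12 of 22 cholesterol synthesis genes (14 adjusted over the list alone; adjusted p = 0.000137). Other lists lost their call with an estimated correlation. NF-kB and inflammatory genes did so with 7 of 35 higher and 2 lower (11 and 2 adjusted over the list alone), at an adjusted p = 0.190. The same held for matrix proteases, 4 and 1 of 19 (7 and 1), at 0.112, and clock genes, 2 and 6 of 19 (5 and 8), at 0.0833. Contractile genes, 2 and 7 of 24 (3 and 8), were lost at 0.154, and Hox genes, 4 and 1 of 28 (5 and 1), at 0.162. Steroid receptor genes, 2 and 0 of 12 (3 and 0), were lost at 0.206, and interferon-stimulated genes, 0 and 3 of 33 (0 and 4), at 0.868. The median and mean differ in sign for NF-kB and inflammatory genes (0.17 and -0.12, tested as higher) and for clock genes (0.02 and -0.28, tested as lower). The liver markers had a median log2 of -1.22 with none of 18 called by edgeR. Of the 2003 genes called in wild type, 1024 were called in this difference. Without the 5 libraries that stood apart 2208 genes were called.

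**Figure D2:**
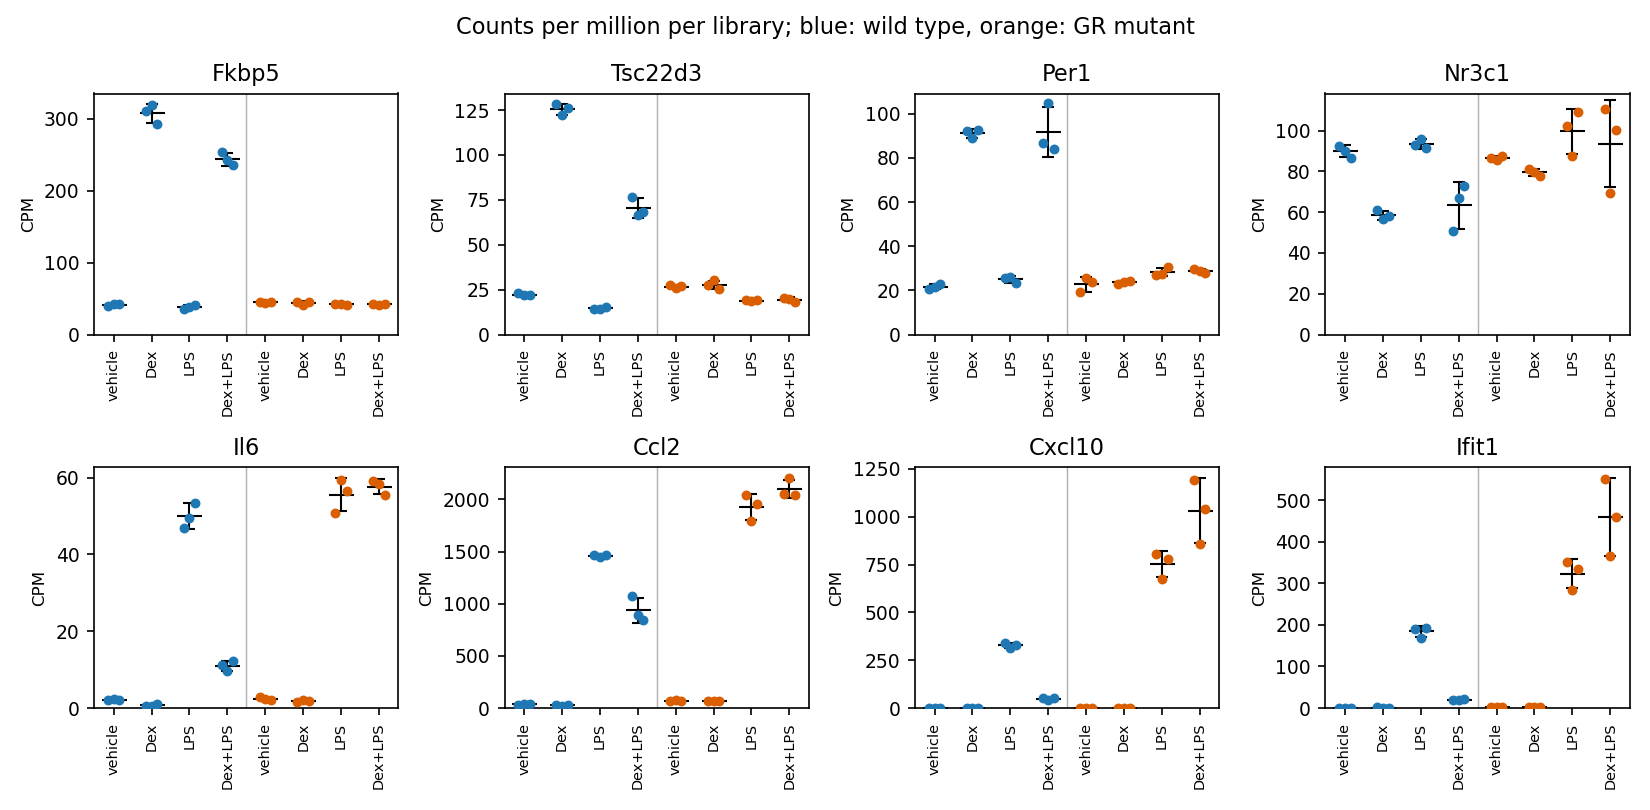
CPM (y axis, linear from 0) of 8 genes in each library, by treatment (x axis), with wild type in blue and the GR mutant in orange. Points are the 3 libraries of a group, and the bar with its whiskers is their mean and SD; Fkbp5 reaches 307 and 244 CPM with Dex in wild type and stays at 41.8 to 44.8 CPM in the mutant.

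LPS induced inflammatory and interferon-stimulated genes in both genotypes. In wild type the neutrophil chemokine Cxcl1 rose 195-fold to 307 ± 12 CPM (SD, n = 3), the monocyte chemokine Ccl2 42.1-fold to 1462 ± 8.08 CPM, Il6 23-fold to 50 ± 3.29 CPM, and Mmp13 by a log2 of 3.96. Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) rose 300.2-fold to 328 ± 14.3 CPM, and Ifit1 (chromosome 19, 34640871 to 34650009), a sensor of viral RNA, 186-fold to 184 ± 12.9 CPM. Among the largest rises were the itaconate-producing enzyme gene Acod1 (802-fold), Rsad2 (log2 10.11), Il1b (at least 826-fold) and Il12b (at least 232-fold), both from 0 reads. With 1 to 3 reads in vehicle, the ratio was 1577 for Nos2 (interval 436 to 13028), 1205 for Cxcl2 (412 to 5844), 1735 for Gbp5 (311 to 68562) and 1553 for Il1a (278 to 61380). Of 35 NF-kB and inflammatory genes 34 rose in wild type and 34 in the mutant (34 in each adjusted over the list alone), with median log2 values of 3.64 and 4.16 (adjusted p = 1.37e-11 and 3.96e-09). All 33 interferon-stimulated genes rose in both, also adjusted over the list alone, with medians of 5.27 and 4.94 (adjusted p = 2.21e-05 and 1.22e-05). In total 4020 genes were called in wild type (2126 higher, 1894 lower) and 5586 in the mutant (2887 higher, 2699 lower). The fit of the compared libraries alone called 6983 genes in wild type, and the fit without the 5 libraries that stood apart 6655.

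Matrix proteases rose with LPS as well, with 10 of 19 members of their list higher and 3 lower in wild type and 12 and 3 in the mutant (10 and 3, and 12 and 4, adjusted over the list alone; adjusted p = 0.00939 and 0.01). Stromelysin 2 (Mmp10) rose by a log2 of 4.23 in wild type and 5.50 in the mutant, Mmp3 by 3.86 and 4.48, Mmp9 by 2.71 and 3.46 and the AP-1 factor Fosl1 by 1.22 and 1.54. Of the p53 target genes 8 of 22 rose and 1 fell in wild type (10 and 1 adjusted over the list alone; adjusted p = 0.00425), led by the death receptor Fas (log2 2.65). In the mutant 9 rose and 4 fell (13 and 4; adjusted p = 0.0173). Hox and limb patterning genes fell, with 20 of 28 lower in wild type and 23 in the mutant (22 and 24 adjusted over the list alone; adjusted p = 0.00212 and 0.000941). Hoxa10 (log2 -1.29 and -1.40) and Hoxd13 (-1.14 and -1.36) were among those that fell. Cholesterol synthesis genes fell in 13 of 22 members in wild type and 16 in the mutant, where 1 rose (14, and 18 against 2, adjusted over the list alone; adjusted p = 0.0165 and 0.00394). Dhcr7 (log2 -0.58 and -0.87) and Insig1 (-0.49 and -0.70) were among them. Of the 31 glucocorticoid-induced genes 9 rose and 7 fell in wild type (10 and 9 adjusted over the list alone), at an adjusted p = 0.0896 with an estimated correlation. In the mutant 10 rose and 5 fell (10 and 5), at an adjusted p = 0.0512 with an estimated correlation. In wild type the median (-0.04) and mean (0.32) of that list differ in sign. Its rises include Nfkbia (log2 3.39), which is also an NF-kB target, while Tsc22d3 (-0.60) and Sgk1 (-0.27) fell. Other large falls in wild type were the chemokine receptor Cx3cr1 (log2 -2.83), Palmd (-2.75), the stem cell marker Lgr5 (-2.67), Tlr13 (-2.57), Wscd2 (-2.20) and the adrenergic receptor Adra1d (-2.06). Mup3 (log2 -2.57, adjusted p = 0.0477) and Adh1 (-2.18, adjusted p = 0.0297), genes abundant in adult liver, also fell in wild type, where the 18 liver markers had a median log2 of -2.31 with 1 lower. With the liver marker level in the fit, the log2 change of Mup3 was -0.61 (adjusted p = 0.264) and that of Adh1 -1.33 (adjusted p = 0.1).

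Across genes, which are not independent replicates, the LPS effects of the genotypes correlated at r = 0.871, with 1864 genes higher and 1522 lower in both against 403 and 336 for independent lists, and 4 called in opposite directions. Without the filter this r was 0.367. The test of the genotype difference of the LPS effect called 82 genes, 53 with a higher and 29 with a lower response in the mutant. Cxcl1 (log2 difference -1.70 ± 0.16, adjusted p = 7.00e-06), Cxcl5 (-1.35 ± 0.17) and Ccl2 (-0.62 ± 0.11, adjusted p = 0.0113) rose by a smaller fold in the mutant, from higher vehicle levels. The level reached with LPS was not lower there for Cxcl1 and Ccl2. Cxcl1 stood at 355 to 359 CPM in the mutant LPS libraries against 298 to 321 CPM in wild type. Ccl2 stood at 1789 to 2040 against 1453 to 1468 CPM. The NF-kB inhibitor gene Tnfaip3 (1.10 ± 0.11), Lif (0.74 ± 0.08), Mmp10 (1.26 ± 0.23), Mmp9 (0.74 ± 0.13), Mmp3 (0.62 ± 0.13), the mRNA decay factor Zfp36 (0.51 ± 0.09) and the cartilage factor Sox9 (0.70 ± 0.16) had higher responses. The matrix protease list, with 3 of 19 members higher (6 higher and 2 lower adjusted over the list alone), was lost at an adjusted p = 0.0557 with an estimated correlation. Glucocorticoid-induced genes, with 1 of 31 higher (3 adjusted over the list alone), kept an adjusted p of 0.0449. Cholesterol synthesis genes (median log2 -0.15, adjusted p = 0.00737) and Hox genes (median -0.17, adjusted p = 0.0331) ranked lower with no member called by edgeR over all genes, and 6 and 1 adjusted over the list alone. Proliferation genes (median -0.08) had no member called either way and were lost at an adjusted p = 0.154 with an estimated correlation. The differences of Il6 (-0.05 ± 0.18), Cxcl10 (1.12 ± 0.32) and Ifit1 (-0.42 ± 0.40) did not pass the test. The count depended on the fit: DESeq2 called 149 genes, the fit without the 5 libraries that stood apart 414, and leaving out mutant vehicle replicate 1 alone left 36.

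Dex given with LPS lowered interferon-stimulated and inflammatory genes in wild type. All 33 interferon-stimulated genes fell (33 adjusted over the list alone), with a median log2 of -2.09, which is 4.27-fold (adjusted p = 0.000288). Ifit1 fell 9.40-fold, from 184 ± 12.9 to 19.4 ± 1.60 CPM (SD, n = 3; log2 -3.23 ± 0.17, adjusted p = 7.43e-12). Cxcl10 fell 6.68-fold to 49.0 ± 5.16 CPM (adjusted p = 1.36e-13), Mx2, annotated as a polymorphic pseudogene, 9.77-fold, Cxcl9 8.06-fold, Ifi44 by a log2 of -3.03 and Oasl1 by -2.98. Ifit3 (log2 -3.26), Ifit3b (-3.64) and Tgtp2 (-3.12) fell as well, with uncertain values, since each shares reads with a near-identical copy. Of 35 NF-kB and inflammatory genes 26 fell and 2 rose (28 and 2 adjusted over the list alone; median log2 -0.64, adjusted p = 1.17e-05). Il12b, which encodes a subunit of interleukins 12 and 23, fell 15.2-fold, Il6 4.49-fold to 11 ± 1.37 CPM, Il1b by a log2 of -2.62, Tnf 3.22-fold, Lif 3.09-fold, Ccl2 1.56-fold and Cxcl1 1.44-fold. Matrix proteases and AP-1 factors fell in 10 of 19 members and rose in 2 (10 and 2 adjusted over the list alone; adjusted p = 0.00596), with falls of Mmp13 (4.89-fold), Mmp10 (4.65-fold), Mmp9 (3.91-fold) and Mmp3 (log2 -1.42). In all 3198 genes were called, 1591 higher and 1607 lower, of which 284 and 297 changed at least 2-fold.

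Dex under LPS raised the glucocorticoid-induced genes of wild type, 24 of 31 higher and 1 lower (24 and 1 adjusted over the list alone; median log2 0.92, adjusted p = 1.04e-08). Fkbp5 rose 6.46-fold to 244 ± 9.01 CPM (SD, n = 3; log2 2.69 ± 0.06), Tsc22d3 by a log2 of 2.26, Per1 by 1.87, Sgk1 by 1.51 and Dusp1 by 0.62. Zbtb16 rose at least 158-fold, from 0 reads, and Map7d2 (16.5-fold), the acute phase genes Serpina3n (14.1-fold) and Lcn2 (7.80-fold), Dlk2 (log2 2.88) and Fam107a (2.81) were among the largest rises. So were Aldh1a7 (log2 4.61) and Aldh1a1 (4.37), which share reads. Cholesterol synthesis genes rose in 17 of 22 members (19 adjusted over the list alone; adjusted p = 3.91e-05), for instance Lss (log2 0.66) and Msmo1 (0.64). Adipogenic genes rose in 6 of 20 (8 higher and 2 lower adjusted over the list alone; adjusted p = 0.0133), for instance Klf15 (3.01) and Fabp4 (2.62). Of 19 clock genes 8 rose and 3 fell (8 and 4 adjusted over the list alone), including Per2 (2.34) and Nr1d1 (-1.47), at an adjusted p = 0.0933 with an estimated correlation. Contractile genes rose in 8 of 24 members and fell in 3 (11 and 3), at an adjusted p = 0.266 with an estimated correlation. Of 12 steroid receptor genes 5 fell (6 lower and 1 higher), at an adjusted p = 0.230 with an estimated correlation. The liver markers had a median log2 of 1.91 with none of 18 called by edgeR. The count of calls was 5050 without the 3 deeper libraries, and 1501 with only the 6 compared libraries in the fit.

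In the GR mutant under LPS, edgeR called 1 gene with Dex. H2-T22, a non-classical MHC class I gene (ENSMUSG00000056116, chromosome 17, 36037128 to 36042747), went from 105 ± 2.79 to 135 ± 6.05 CPM (SD, n = 3; log2 0.36 ± 0.06, adjusted p = 0.0427). At an unadjusted p below 0.05 there were 889 genes, and DESeq2 called 31. Fkbp5 was at 41.8 ± 1.22 CPM with LPS and 41.9 ± 0.844 CPM with Dex and LPS, Il6 at 55.5 ± 4.28 and 57.6 ± 1.92 CPM, and Ifit1 at 323 ± 35.1 and 459 ± 92.8 CPM (log2 0.51 ± 0.15, adjusted p = 0.386). Interferon-stimulated genes ranked higher with Dex in the mutant, at a median log2 of 0.46 (adjusted p = 0.00493), with 0 of 33 members called by edgeR over all genes and 26 higher adjusted over the list alone. Without the 2 libraries that differed by transcript length, 90 genes were called, 18 of these list members among them, and without mutant Dex and LPS replicate 2 alone 30 genes were called. Without any other of the 6 compared libraries, without the 3 deeper libraries, with only the compared libraries in the fit, or with the liver marker level in the fit, edgeR called 0 genes and the call of H2-T22 was lost. With library series as a covariate 2 genes were called, without a filter 6 and with the replicate number as a block 11, all higher. Cholesterol synthesis genes ranked higher too (median 0.07, adjusted p = 0.0102), with 0 members called by edgeR (2 adjusted over the list alone). The median of NF-kB and inflammatory genes was 0.05, with 0 called by edgeR (1 adjusted over the list alone), at an adjusted p = 0.338 with an estimated correlation. Skeletal muscle markers had a median of -0.34 with 0 of 7 called by edgeR, also adjusted over the list alone, at an adjusted p = 0.104 with an estimated correlation. Over the 3198 genes called in wild type the Dex score moved by 1.26 in wild type and by 0.000717 in the mutant (95% interval -0.196 to 0.197; exact permutation p = 1, smallest possible 0.1), with the wild-type value inflated in the same way. The liver markers had a median log2 of -2.17 with none of 18 called by edgeR.

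The genotype difference of the Dex effect under LPS was called for 1581 genes, 816 higher and 765 lower in the mutant. All 33 interferon-stimulated genes had a higher response (33 adjusted over the list alone; median log2 2.50, adjusted p = 2.77e-05), such as Ifit1 (3.74 ± 0.22), Cxcl10 (3.19 ± 0.15) and Mx2 (3.81 ± 0.16). Of 35 NF-kB and inflammatory genes 25 had a higher and 2 a lower response (27 and 2 adjusted over the list alone; adjusted p = 4.37e-06), including Il6 (2.22 ± 0.13), Lif (1.69 ± 0.08) and Ccl2 (0.76 ± 0.11). Of 19 matrix proteases and AP-1 factors 8 had a higher and 1 a lower one (10 and 3; adjusted p = 0.00324), including Mmp13 (2.58 ± 0.63). Glucocorticoid-induced genes had a lower response in 24 of 31 members and a higher one in 1 (24 and 1; adjusted p = 2.11e-07), with Fkbp5 at -2.69 ± 0.08 and Tsc22d3 at -2.23 ± 0.10. A lower response was also called for 12 of 22 cholesterol synthesis genes (17; adjusted p = 0.000328) and 3 of 20 adipogenic genes (4 lower and 2 higher; adjusted p = 0.0184). Contractile genes, with 5 of 24 lower and 2 higher (7 and 3), were lost at an adjusted p = 0.325 with an estimated correlation. Clock genes, with 8 of 19 lower and 3 higher (8 and 3), were lost at an adjusted p = 0.0642 with an estimated correlation. Of the 18 liver markers 2 were lower, at a median log2 of -4.12. Of the 3198 genes called in wild type, 1506 were called in this difference. Leaving out the 5 libraries that stood apart left 1 library of wild type with Dex and LPS, so no count is given for that fit. With only the compared libraries in the fit 1039 genes were called.

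Genes induced by LPS were followed as a set chosen in the other genotype, so that no library served both to choose and to measure. Of 721 genes induced in the mutant, 400 fell, 52 rose and 269 were not called with Dex under LPS in wild type, and their median log2 was -0.56, a 1.48-fold decrease (SD between replicates 0.0218, n = 3). Of 576 genes induced in wild type, 1 rose and none fell with Dex under LPS in the mutant by edgeR, at a median log2 of 0.07 (SD 0.0613, n = 3), and 0.12 without mutant Dex and LPS replicate 2. The wild-type median was -0.11 over genes with any called rise, of which 914 fell, and -1.04 over genes induced more than 4-fold, of which 232 fell. In wild type, the Dex effects with and without LPS correlated across genes at r = 0.318. Leaving out 1 library gave 0.254 (without wild-type Dex and LPS replicate 1) to 0.494 (without replicate 3), and dropping the filter gave 0.0653. They shared 896 higher and 540 lower genes against 126 and 84.3 for independent lists, and 20 were called in opposite directions.

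**Figure D3:**
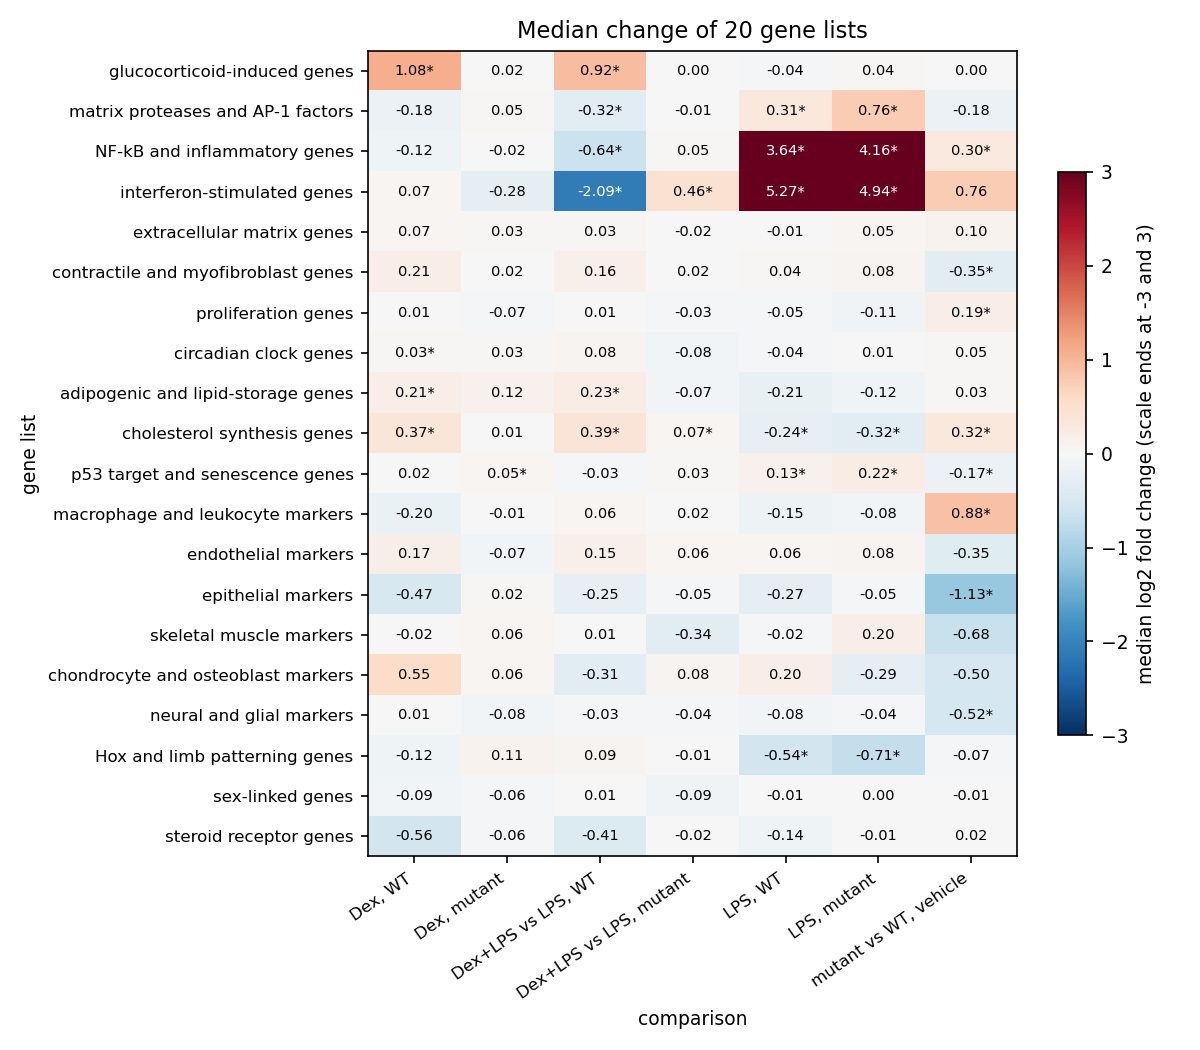
Median fitted log2 fold change of 20 gene lists (y axis) in 7 comparisons (x axis), with color from blue (lower) to red (higher) and the value written in each cell. A star marks an adjusted p below 0.05 with the correlation estimated for the list; interferon-stimulated genes stand at 5.27 and 4.94 with LPS and at -2.09 with Dex under LPS in wild type.

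The untreated genotypes differed in markers of several cell lineages. Lgr5, a WNT receptor partner that marks stem and mesenchymal progenitor cells (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780), was 13.1-fold higher in the mutant, at 35.8 ± 2.89 against 2.74 ± 0.567 CPM (SD, n = 3; log2 3.72 ± 0.11, adjusted p = 5.19e-16). The repressor gene Prdm1 (10.8-fold), the chemokine Cxcl5 (9.42-fold), Wisp2 (7.22-fold), the matrix gene Dpt (5.48-fold), Adh7 (log2 2.83), U90926 (2.72) and Bcl11b (2.55) were among the largest differences toward the mutant. Rgs5, a marker of pericytes (ENSMUSG00000026678, chromosome 1, 169655501 to 169695813), was 9.42-fold lower, at 5.87 ± 0.481 against 56.1 ± 0.345 CPM. P-selectin (Selp, 6.60-fold), endomucin (Emcn, 4.88-fold), Hist1h3b (log2 -2.48), Pappa2 (-2.26), Dusp27 (-2.26) and the retinaldehyde dehydrogenase Aldh1a2 (-2.26) were lower too. Fam107a was lower at 3 against 15 reads, a ratio of 7.44 (interval 2.10 to 40.1). In total 2861 genes were called, 1322 higher and 1539 lower, of which 290 and 319 differed at least 2-fold. Fkbp5 (log2 0.12 ± 0.05, adjusted p = 0.154), Per1 (0.05 ± 0.09), Dusp1 (0.03 ± 0.07), Il6 (0.20 ± 0.16), Cxcl10 (0.08 ± 0.29) and Mmp13 (-0.67 ± 0.79) were not called. Tsc22d3 (0.27 ± 0.07), Sgk1 (0.25 ± 0.05), Ccl2 (1.01 ± 0.08), Cxcl1 (1.92 ± 0.14) and Ifit1 (1.23 ± 0.37) were higher in the mutant. Ifit1 stood at 3.21 CPM in the deeper mutant replicate 1 and at 1.47 and 1.39 CPM in replicates 2 and 3, against 0.807 to 1.28 CPM in wild type. Without the 5 libraries that stood apart 4621 genes were called, and the liver markers had a median log2 of -0.31 with none of 18 called by edgeR.

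Leukocyte markers were higher in mutant vehicle cultures in 16 of 18 tested members and lower in none (17 and 0 adjusted over the list alone; median log2 0.88, adjusted p = 2.36e-05). The lysozyme gene Lyz2 stood at 118 ± 6.92 against 46.0 ± 1.37 CPM (SD, n = 3), the macrophage growth factor receptor Csf1r at 25.5 ± 1.76 against 10.6 ± 0.351 CPM, and Adgre1 and Laptm5 differed by a log2 of 1.40 and 0.95. Moving with these markers, NF-kB and inflammatory genes were higher in 12 of 35 members and lower in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.0218), including Ccl7 (log2 1.05) and Il1rl1 (1.07). Interferon-stimulated genes were higher in 14 of 33 (19 adjusted over the list alone), including Oas1a (log2 1.71), Rtp4 (1.41), Xaf1 (1.18) and Parp14 (1.12), at an adjusted p = 0.485 with an estimated correlation. The mutant vehicle libraries were spread for this list, with a mean log2 CPM of 1.3 in the deeper replicate 1, 0.95 in replicate 2 and 0.59 in replicate 3, against 0.24 to 0.42 in wild type. Cholesterol synthesis genes were higher in 16 of 22 members (19 adjusted over the list alone; adjusted p = 0.000137), including Lss (log2 0.46) and Dhcr7 (0.47). Proliferation genes were higher in 15 of 31 (23 higher and 1 lower adjusted over the list alone; adjusted p = 0.01), each by little, such as Mcm3 (log2 0.26), Mcm6 (0.24) and Bub1b (0.23).

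Contractile and myofibroblast genes were lower in 16 of 24 members and higher in 1 in the mutant (18 and 1 adjusted over the list alone; median log2 -0.35, adjusted p = 0.001). The intermediate filament gene Des was 4.28-fold lower, at 13.4 ± 1.36 against 56.9 ± 5.30 CPM (SD, n = 3), and Myh11 (log2 -0.99), Ankrd1 (-0.97) and Ctgf (-0.72) were lower. The p53 target genes Pmaip1 (log2 -1.67), Perp (-1.20), Plk2 (-0.48) and Btg2 (-0.35) led a list with 8 of 22 members lower and 2 higher (9 and 2 adjusted over the list alone; adjusted p = 0.000755). Epithelial markers were lower in 3 of 4 members, also 3 adjusted over the list alone (adjusted p = 0.00371), with the tight junction gene Cldn4 39.9-fold, Krt18 by a log2 of -1.60 and Krt19 by -0.65. Nerve and glia markers were lower in 4 of 11 members and higher in 2 (4 and 3 adjusted over the list alone; adjusted p = 0.0176), with Nes (log2 -1.41) lower and Sox10 (2.16) higher. Endothelial markers were lower in 3 of 8 and higher in 1, the same adjusted over the list alone, with Kdr (log2 -1.02) lower and Flt1 (0.70) higher, at an adjusted p = 0.0567 with an estimated correlation. Cartilage and bone markers were lower in 6 of 18 and higher in 2, also adjusted over the list alone, including Col2a1 (log2 -2.15) and Sox5 (-0.86), at an adjusted p = 0.351 with an estimated correlation. Extracellular matrix genes were higher in 10 of 31 and lower in 7 (11 and 7 adjusted over the list alone), with Col15a1 (log2 1.99) and Col6a2 (1.41) higher and Loxl2 (-0.70) lower, at an adjusted p = 0.167 with an estimated correlation. Lists not called were skeletal muscle markers, with 3 of 7 lower (Tnni1, log2 -1.49), Hox genes, with 6 of 28 higher and 8 lower (Hoxd8, 1.03; Hoxa5, -1.24), and sex-linked genes, with 1 of 5 lower (Eif2s3y, -0.21). The counts adjusted over the list alone were 3, 7 and 11, and 1.

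The authors' deposited table for Dex in wild type holds 1888 called genes, 1122 higher and 766 lower, of which 1757 were also called here in the same direction. For Dex under LPS in wild type the authors' deposited table holds 3059, 1442 higher and 1617 lower, of which 2814 were also called here. In the mutant the authors' deposited table calls 3 genes with Dex, 2 higher (Zfp36 and Egr1) and 1 lower (6720427I07Rik), of which 0 were called here by edgeR. Under LPS the authors' deposited table calls 28 in the mutant, 27 higher, of which 1 was called here. These mutant genes are named because the count is small, after their values were seen. Across the 12536 genes tested in both, the log2 fold changes correlated with those computed here at r = 0.992 and 0.993 in wild type and 0.981 and 0.980 in the mutant, without and with LPS.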

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

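The tests of NF-kB genes in the mutant, of the liver transcripts and of a lower fibroblast share, and the comparison of the Dex effect with and without LPS in wild type, were chosen only after the result was seen. For the other tests the prediction was written before the result of that test. The interferon and leukocyte patterns they address, and the library that differed by transcript length, were themselves picked after the data were seen. The genotype differences below are listed because the difference between the genotypes itself passed the test. The planned test for a single library far from its group was not applied, since it needs groups of at least 4. The 3 later-series libraries were set apart by their labels, and the 2 that differed by transcript length after the data were seen.

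The Dex effect differed between genotypes for 1064 genes. Named genes were Fkbp5 (log2 difference -2.92), Tsc22d3 (-2.45), Per1 (-2.00), Sgk1 (-1.46), Cxcl1 (-0.78) and Dusp1 (-0.40), lower in the mutant, and Il6 (1.17) and Ccl2 (0.42), higher. Under LPS it differed for 1581 genes, with Fkbp5 at -2.69, Tsc22d3 at -2.23, Per1 at -1.84, Sgk1 at -1.46 and Dusp1 at -0.41, and with Ifit1 at 3.74, Cxcl10 at 3.19, Mmp13 at 2.58, Il6 at 2.22, Ccl2 at 0.76 and Cxcl1 at 0.57. The LPS effect differed for 82 genes, including Cxcl1 (-1.70) and Ccl2 (-0.62). In wild type, the Dex effect with LPS differed from that without LPS for 238 genes.

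Other splits of the 6 libraries of each comparison are too few, at 10, for a share under 0.05. The real grouping was the 1 split with a count as large for Dex in wild type (2003 genes; highest other 0), Dex under LPS in wild type (3198; 0), LPS in wild type (4020; 0), LPS in the mutant (5586; 0), the genotypes in vehicle (2861; 0) and Dex under LPS in the mutant (1; 0). For Dex in the mutant all 10 of 10 splits gave 0 genes by edgeR, where 1109 genes had an unadjusted p below 0.05 and DESeq2 called 3. For the LPS-induced genes, 1 of 10 splits gave a median as large in wild type (0.565; highest other 0.233) and 3 of 10 in the mutant (0.0703; highest other 0.0914). For the differences, 100 splits were drawn, and 6 gave as many genes for Dex (highest other 1350), 5 for Dex under LPS (3253), 10 for LPS (6783) and 10 for the Dex effect with against without LPS in wild type (4000). These shares are at least 0.05, so the count of splits does not exclude chance. All of the other splits as large kept the libraries of a group pair whole, which shows the structure of the samples, and the 83 splits mixed in both pairs gave at most 0 genes by edgeR.

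Interferon-stimulated genes had a median log2 of 0.46 with Dex under LPS in the mutant. Leaving out mutant Dex and LPS replicate 2, which differed by transcript length, gave 0.573, above the bound of 0.229 by more than the SD between replicates (0.240). That library had the lowest mean log2 CPM of the list in its group, 6.08 against 6.56 and 6.38. Leaving it out was thus set to raise the difference, so the bound decides nothing, and the values show only that the rise did not rest on this library. A stronger LPS stimulus in the mutant Dex and LPS cultures was taken to raise NF-kB and inflammatory genes too, and their median was 0.0461 (SD 0.0344, bound 0.114). No other LPS dose was used, so it is not known whether these genes, already induced by LPS, could rise further. A stronger stimulus is thus not excluded. Leaving out mutant LPS replicate 2, from the later library series, gave 0.379, above the bound by less than the SD, so its part stays open. A biological effect of Dex through the mutant receptor stays open as well, and was not tested.

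Transcripts of adult liver varied between libraries of the same group, by a median of 6.56-fold from lowest to highest (range 1.13 to 118), which argues against a response to genotype or treatment. Liver cells left from the embryos would bring Afp, but its upper limit was 0.193% of Alb (43 against 30078 reads in 19 libraries). The other 17 markers followed Alb over the 24 libraries, with a median rank correlation of 0.916, so RNA or reads from an adult liver sample carried into the libraries may be the source.

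Leukocyte markers were higher in mutant vehicle cultures, with 16 of 18 called and the fitted value of each of the 18 above 0. Their log2 differences varied by an SD of 0.222 beyond their standard errors, under the bound of 0.5, so a larger share of leukocytes in those cultures is a candidate explanation. A lower share of fibroblasts would raise the markers of the other cell types alike. Of the 4 other lists tested, skeletal muscle markers had the lowest median, -0.676. The median SE of their single members was 0.297, which is not an SE of the list median, and that list was not called. The medians of nerve and glia (-0.518), cartilage and bone (-0.497) and endothelial markers (-0.353) were also below 0. Genotype cannot be told apart from the embryos and cultures that carried it, so an effect of the mutation on leukocytes was not tested.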

How the results depend on the processing

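Leaving out the 2 libraries that differed by transcript length, alone or with the 3 later-series libraries, the liver marker level as covariate, and the added comparison were chosen only after the result was seen. No called result reversed, and 472 of 551 called gene results kept their direction and side of the threshold in every alternative. Size factors by relative log expression, unstranded counts and no robust estimation moved none of the 19 summary results they were applied to. Without the 5 libraries: Dex in wild type 4331 genes, in the mutant 5, their difference 2208, Dex under LPS in the mutant 164, its difference 2967, LPS in wild type 6655, its difference 414, vehicle 4621, the added comparison 795, LPS-induced median -0.59, 1 lower in the mutant, LPS r 0.813, shared Dex calls 2369. Without the 2: Dex in the mutant 1, difference 1692, Dex under LPS in the mutant 90, LPS difference 261, added comparison 391, LPS-induced median -0.53, 1 lower in the mutant. Without the 3 later-series libraries: Dex in the mutant 1, Dex under LPS in wild type 5050 and in the mutant 0, added comparison 392, LPS r 0.813, Dex r 0.496. With only the compared libraries, which are fewer: 4697, 1634, 1501, 0, 1039, 6983 and 137 genes for Dex in wild type, its difference, Dex under LPS in wild type, in the mutant, its difference, LPS in wild type and its difference. DESeq2 called 3 and 31 genes in the mutant without and with LPS, and 149 in the LPS difference. Series as covariate gave 2 genes under LPS in the mutant, 134 in the LPS difference, an LPS-induced median of -0.52 and Dex r 0.467, and liver level 0, 145 and Dex r 0.537. Without a filter, 6 genes were called under LPS in the mutant, and r fell to 0.367 (LPS) and 0.0653 (Dex). The stricter filter gave an LPS-induced median of -0.59. LPS-induced genes at any rise gave -0.11 (914 lower) in wild type and 0.00128 in the mutant, and above 2 on the log2 scale -1.04 (232 lower) and 0.14. With an estimated correlation 44 of the 200 list tests were called. Replicate numbers do not pair the samples (36 same-number correlations, median 0.0199), and with them as a block 11 genes were called under LPS in the mutant. The cause was not tested for these moves.

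Leaving out 1 library at a time gave 1517 to 1625 genes for Dex in wild type, 0 to 0 in the mutant by edgeR, 878 to 1020 for their difference, 2424 to 4481 for Dex under LPS in wild type, 0 to 30 in the mutant (30 without MUT_DexLPS replicate 2), 1270 to 1924 for the difference, 3222 to 3360 and 4646 to 5322 for LPS in wild type and mutant, 36 to 82 for their difference (36 without MUT_CTR replicate 1), 2255 to 2579 in vehicle and 156 to 316 for the added comparison (156 without WT_Dex replicate 2). LPS-induced medians were -0.59 to -0.50 (351 to 404 lower) and 0.05 to 0.12 (0 to 0), LPS r 0.774 to 0.878 (2861 to 3378 shared) and Dex r 0.254 to 0.494 (1177 to 1549 shared). Depth limits genes near 0.0518 to 0.159 CPM, where 3 reads lie.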

Other observations

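The comparison of the Dex effect with and without LPS in wild type, the genes named from it, and the test of the share of the LPS rise were chosen only after the result was seen.

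The size or direction of the Dex effect in wild type differed with LPS for a set of genes. The difference was called for 238 genes, 48 higher and 190 lower under LPS, of which 104 were also called for Dex alone, 214 for Dex under LPS and 20 for both with opposite signs. The count fell to 156 without wild-type Dex replicate 2. It rose to 391 without the 2 libraries that differed by transcript length and 392 without the 3 later-series libraries. Without all 5 only 1 library of wild type with Dex and LPS was left, so no count is given. Of the interferon-stimulated genes 26 of 33 were lower (median log2 -2.06, adjusted p = 0.000105), such as Ifit1 (-3.39), Ifi44 (-2.89), Cxcl10 (-2.52) and Stat2 (-1.63). Without LPS this list was low, at a mean log2 CPM of 0.24 to 0.42 with vehicle and 0.34 to 0.48 with Dex. Its median Dex effect was 0.07 without LPS and -2.09 under LPS, so the difference mostly restates the fall of LPS-induced levels. NF-kB and inflammatory genes were lower in 7 of 35 members (adjusted p = 0.001), such as Cxcl1 (-1.21), which rose with Dex alone and fell under LPS, and Lif (-1.09). Matrix proteases were lower in 4 of 19 (adjusted p = 0.0429), led by Mmp9 (-1.78). Slc15a3 (1.72), Tlr13 (1.64) and Palmd (1.08) were higher. Glucocorticoid-induced genes, with 1 of 31 higher and 3 lower, were lost at an adjusted p = 0.0918 with an estimated correlation. Leukocyte markers, with 1 of 18 higher (median log2 0.23), were lost at 0.159 in the same way. Cartilage and bone markers (median log2 -0.75) and Hox genes (0.16), with no member called by edgeR, were lost at 0.292 and 0.0990. The 18 liver markers had a median log2 of 3.70 with none called by edgeR.

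Interferon-stimulated genes fell with Dex by a median of 44.7% of their LPS rise on the log2 scale, and NF-kB and inflammatory genes by 13.9%, over 33 and 34 genes that rose, with the rise measured in the mutant. A permutation of the genes between the lists gave p = 1e-05, the smallest that 100000 permutations can give. This argues against a stronger LPS rise of interferon-stimulated genes as the only cause of their larger fall. Genes of a list move together, so the permutation of genes overstates the certainty, and the cause stays open.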
